A study of Sus scrofa with 24 samples.

How the data were processed

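Ovaries of healthy pigs of the Chenghua breed were sampled at 4 stages, with 3 sows per stage: postnatal day 3, postnatal day 120 (called Puberty), 1 year of age (Year 1) and day 105 of pregnancy. The labels describe the ovaries as cut into fragments that were frozen for RNA extraction, and mRNA was captured on oligo(dT) beads. The 12 mRNA libraries were compared; the 12 small RNA libraries named in the labels were not analysed here. Each library came from a different sow, so p-values rest on the spread between libraries of a stage. That spread can hold differences between the fragments sampled as well as between sows. In the main test it was pooled over all 4 stages, which differed in spread, as given below. A p-value for any pair of stages therefore also drew on the libraries of the other stages.

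Per the submitters' processing notes, the mRNA reads were aligned with Bowtie2 2.3.4.3 to Sscrofa11.1, quantified with RSEM 1.3.1 and tested with DESeq2 1.4.5. The authors deposited RSEM expected counts per gene and library, which need not be whole, and TPM values for the same genes and libraries. The deposited table also holds the authors' log2 fold changes for each pair of stages and the authors' q-values from DESeq2. It lists 18753 genes, all of which matched the RefSeq gene table by identifier.

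The expected counts were rounded to whole numbers. Between 92.956% and 94.678% of the values in a library were already whole. Library totals ran from 14615474 to 16187915 counts, a ratio of 1.11, and 15788 to 17702 genes were detected per library. TPM served to give levels per library and was not tested. Genes were kept by edgeR's filterByExpr with a minimum count of 10, which left 15699 genes. Counts were scaled with TMM, whose factors ran from 0.75 to 1.25.

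The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with 1 term per stage and all 12 libraries in 1 fit, so that the stages shared 1 estimate of spread per gene. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The square root of the common dispersion was 0.4. Each pair of stages was tested, and so was a difference among any of the 4 stages. A total of 27 gene lists were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. KEGG terms in the deposited table with 10 to 300 members were tested with Fisher's exact test, one-sided, against the 6354 annotated genes tested; this enrichment was added after seeing the data.

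The gene lists, the edgeR and camera tests and the rule for named genes were set before the data were examined; the KEGG test and the tests of technical explanations, other than the counts of other splits, were chosen afterwards. The rule took, for each pair of consecutive stages, the 5 largest rises and 5 largest falls among genes past the threshold with a mean log2 CPM of at least 3, no overlap between the libraries of the 2 stages and an informative symbol. It also took the lowest adjusted p in each list, 2 genes in each of 10 core ovarian lists and 1 in each other list, and a fixed set of 11 genes of steroid synthesis, follicles, oocytes and luteal tissue. RLN2, MSMB, TIMP1, INHA, ZP2, COL4A2, COL3A1, SPARC, VSIG4 and the oviduct and rete markers were named outside the rule after values were seen, as were COL4A1, VCAN, MAEL and GTSF1 in Pregnancy vs Year 1.

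The scripts were tested on simulated counts drawn from the real means, dispersions and library sizes, with 200 changed genes per comparison and 41 other genes of 1 list raised 2-fold. The 200 changed genes were drawn only from genes above a minimum mean count. Recovery was therefore not measured for the genes with the fewest counts. For Puberty vs Day 3, run on 15458 genes, edgeR recovered 10 of 67 genes changed 2-fold, 50 of 67 changed 4-fold and 51 of 66 changed 8-fold, and called 3 of the 15217 unchanged genes tested. For Year 1 vs Puberty, run on 15454 genes, it recovered 9 of 67, 43 of 67 and 58 of 66 in the same order. For Pregnancy vs Year 1, run on 15460 genes, it recovered 5 of 67, 46 of 67 and 54 of 66. The simulation gave all stages equal spread, which the real libraries did not have.

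Alternatives were other scalings (RLE, upper quartile), no count filter or a minimum count of 50, DESeq2 1.42.0, limma voom with sample quality weights, a fold threshold of 2, a fit of only the 2 stages compared, a term for the replicate number, and leaving out each library in turn. Leaving out Year 1 replicate 1 and Pregnancy replicate 3 together was added after seeing the data. Within stages no pair of libraries agreed to within sampling noise: the chi-square per degree of freedom was at least 18.7.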

Results

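The transcriptome of the pig ovary was followed over 12 mRNA libraries, 3 each at postnatal day 3, at Puberty (day 120), at Year 1 and on day 105 of pregnancy. The design asked how ovarian gene expression differed between successive stages of development and gestation. Of 15699 genes tested, 7220 differed among the 4 stages (edgeR quasi-likelihood test, adjusted p under 0.05). The stage mean was highest at Day 3 for 3295 of these, at Year 1 for 2534, in Pregnancy for 869 and at Puberty for 522. The count of 7220 fell to 4544 without Day 3 replicate 2.

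The libraries of a stage were not equally alike. The median SD of a gene across a stage was 0.18 (log2) at Day 3, 0.25 at Puberty, 0.46 at Year 1 and 0.40 in Pregnancy. The 3 Day 3 libraries lay 0.44 to 0.53 apart (root mean square log2 difference). Year 1 replicate 1 lay 1.63 and 1.34 from its stage mates and 0.61 from Puberty replicate 1. Pregnancy replicate 3 lay 1.20 from both of its stage mates, 1.18 from Year 1 replicate 3 and 1.315 from Year 1 replicate 2. Pregnancy replicates 1 and 2 lay 0.54 apart.

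**Figure D1:**
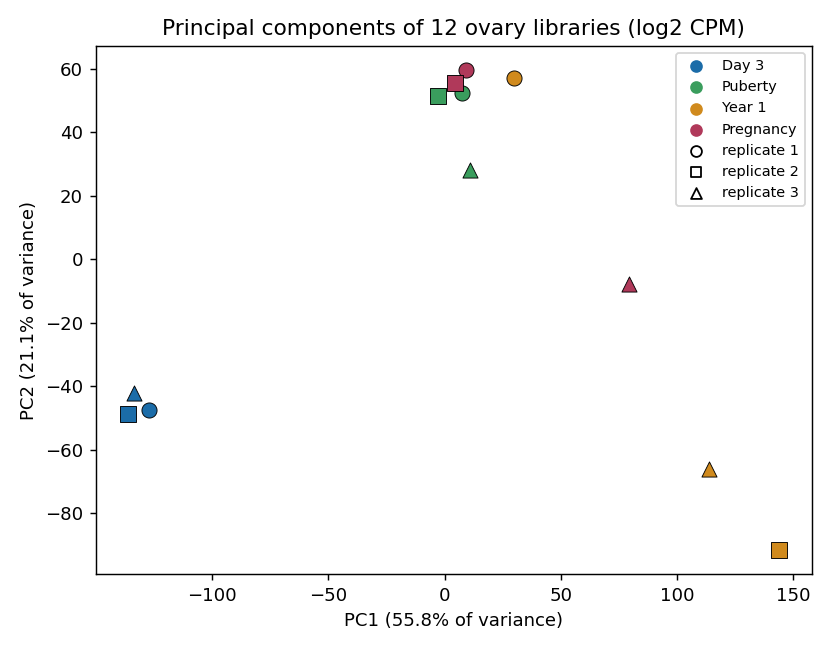
Principal components of log2 CPM; each point is 1 library, colours are stages and shapes are replicates. PC1 (55.8% of the variance) places the 3 Day 3 libraries at -127.1 or below, and Year 1 replicates 2 and 3 at 113.7 or above. Year 1 replicate 1 lies at 29.9, beside the Puberty libraries and Pregnancy replicates 1 and 2 (9.31 and 4.64).

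Steroidogenic and luteal transcripts were among those that set these libraries apart. RLN2, MSMB and INHA were named here after values were seen, and the cholesterol synthesis and oocyte lists also differed between libraries of a stage, as given below. STAR, which carries cholesterol into mitochondria for steroid synthesis (chromosome 15, 48377597 to 48385398, Sscrofa11.1), was at 5294.4 and 5107.3 TPM in Year 1 replicates 2 and 3 and at 50.7 TPM in replicate 1. It was at 3948.6 TPM in Pregnancy replicate 3 and at 5.88 and 11.8 TPM in replicates 1 and 2. HSD3B1, which makes progesterone from pregnenolone, was at 11031.4 and 8605.5 TPM in Year 1 replicates 2 and 3 against 355 TPM in replicate 1, and at 8474.3 TPM in Pregnancy replicate 3 against 142.5 and 144.6 TPM. RLN2, which encodes the luteal hormone relaxin (chromosome 1, 216763546 to 216769802), was the leading transcript of Pregnancy replicate 3 at 49365.1 TPM. It was at 0.22 and 0 TPM in Pregnancy replicates 1 and 2 and at 292.8 and 265.4 TPM in Year 1 replicates 2 and 3. MSMB, a secreted protein, led Year 1 replicates 2 and 3 at 36138.7 and 30835.2 TPM, against 31.7 TPM in replicate 1 and 549.1 TPM in Pregnancy replicate 3. Year 1 replicate 1 instead had the highest INHA, the inhibin alpha subunit of granulosa cells, at 9078.9 TPM, and CYP19A3 at 858.1 TPM, close to the 868 TPM of Puberty replicate 1. CYP19A3 is 1 of several near-identical pig aromatase copies, so its reads are uncertain between copies; CYP19A1 had too few counts to be tested.

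**Figure D2:**
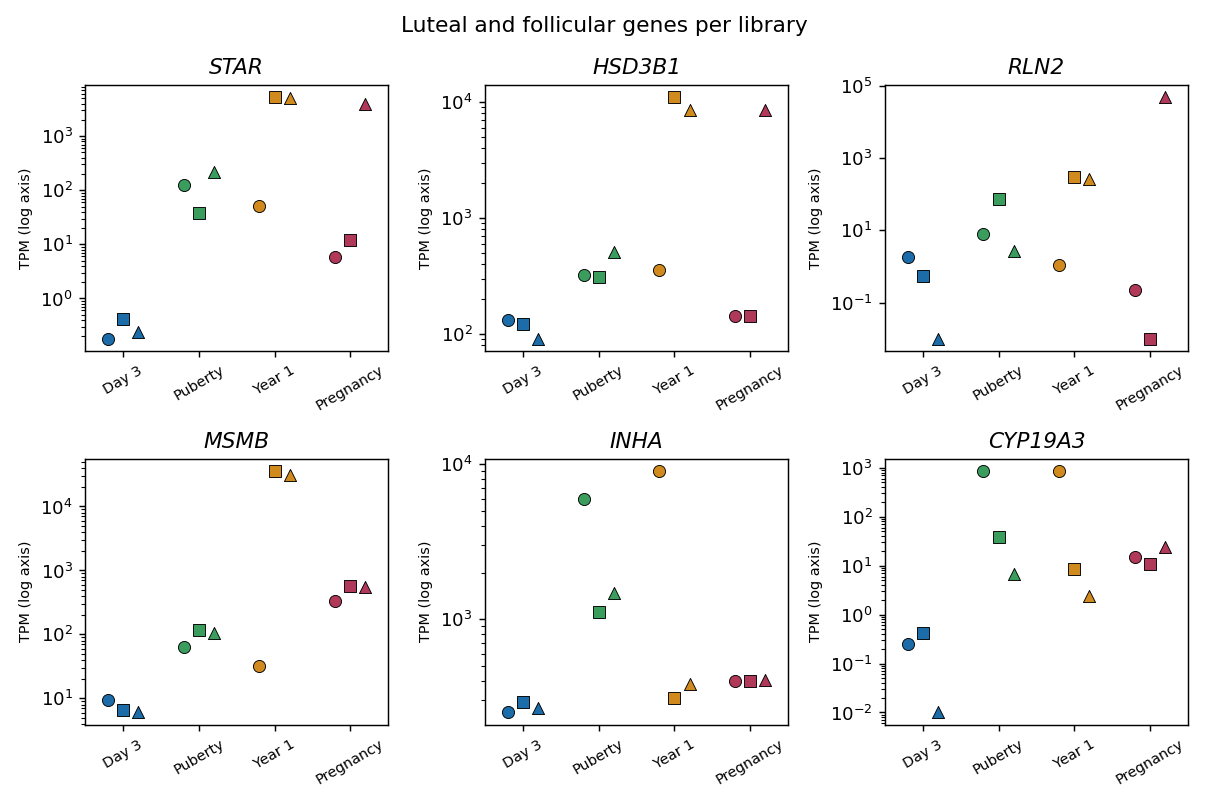
TPM of 6 luteal and follicular genes per library on log axes; each point is 1 library, with values under 0.01 drawn at 0.01. STAR and HSD3B1 are high in Year 1 replicates 2 and 3 and in Pregnancy replicate 3, and RLN2 reaches 49365.1 TPM in Pregnancy replicate 3 alone.

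Between Day 3 and Puberty, 17 of 27 oocyte genes and 16 of 21 meiosis genes fell, and 11 of 22 granulosa genes rose. DDX4, a germ-cell RNA helicase (chromosome 16, 34879701 to 34983701), fell from 119 ± 24.6 to 5.86 ± 0.869 TPM (SD, n = 3), a log2 change of -4.03 ± 0.22 (SE, adjusted p = 3.98e-05). MAEL, of the piRNA pathway, fell by 4.17 ± 0.32 on the log2 scale (adjusted p = 0.000115), and the meiotic cohesin STAG3 fell by 4.02 ± 0.35 (adjusted p = 0.000145). GDF9, an oocyte growth factor, fell from 216 ± 52.4 to 38.9 ± 4.14 TPM, a log2 change of -2.14 ± 0.34 (adjusted p = 0.0019). In the oocyte list 17 of 27 tested members fell and none rose (18 adjusted over the list alone). In the meiosis list 16 of 21 fell and none rose (17 adjusted over the list alone). Camera placed both lists lower at the preset correlation (adjusted p = 5.16e-07 and 1.22e-11); with an estimated correlation the adjusted p = 0.343 and 0.277. ZP2, of the egg coat, did not pass, at 2.03 ± 1.11 (adjusted p = 0.192).

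**Figure D3:**
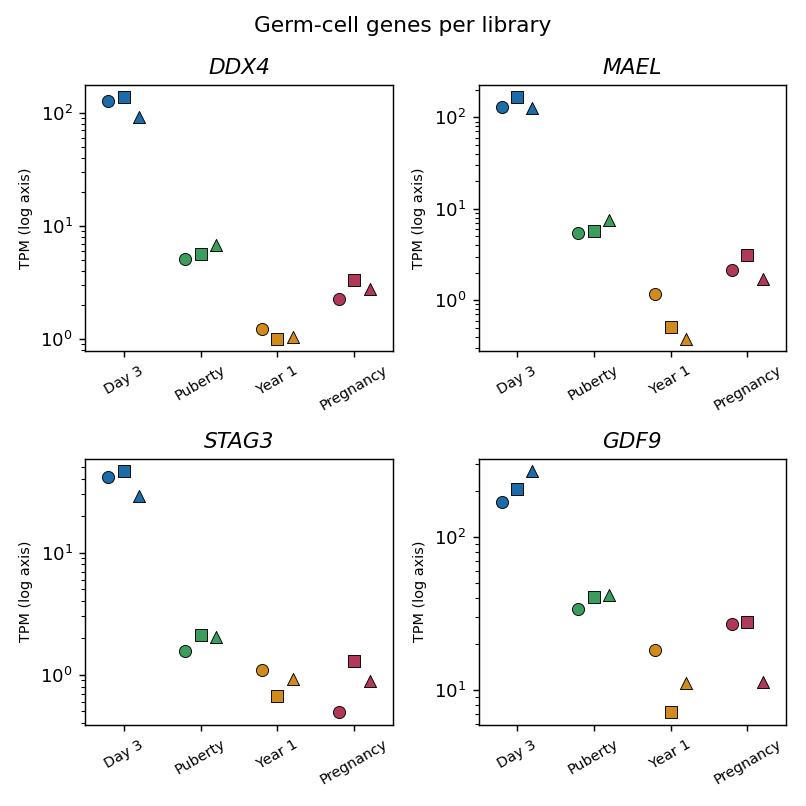
TPM of 4 germ-cell genes per library on log axes; each point is 1 library. DDX4 lies at 90.9 TPM or above in the 3 Day 3 libraries and at 6.79 TPM or below in every other library.

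In the list of granulosa cells, which surround the oocyte, 11 of 22 tested members rose and 3 fell (13 and 4 adjusted over the list alone; camera adjusted p = 0.00204, and adjusted p = 0.595 with an estimated correlation). FST, which encodes the activin-binding follistatin, rose from 18.4 ± 0.927 to 395.8 ± 221 TPM (log2 change 4.79 ± 0.54, adjusted p = 0.000413), and the protease gene HTRA1 rose by 2.47 ± 0.38 (adjusted p = 0.00163). In the theca list 7 of 13 rose and 1 fell (camera adjusted p = 0.00198, and adjusted p = 0.595 with an estimated correlation), with the luteinizing hormone receptor LHCGR at 4.80 ± 0.92 (adjusted p = 0.00435). The androgen-forming enzyme CYP17A1 rose by 8.96 ± 1.84 (adjusted p = 0.00587) and CYP11A1, which makes pregnenolone, by 7.65 ± 1.77 (adjusted p = 0.01). In the steroid synthesis list 9 of 22 rose and none fell (camera adjusted p = 0.000232, and adjusted p = 0.277 with an estimated correlation). In the luteal list 6 of 19 rose and 1 fell (camera adjusted p = 0.00204, and adjusted p = 0.52 with an estimated correlation); 13 of its 19 members also stand in another list. STAR rose by 9.13 ± 2.79 (adjusted p = 0.0325), a call lost on leaving out any 1 of 6 libraries, with the highest adjusted p = 0.106 without Day 3 replicate 3. The largest rises were those of CYP19A3 (10.98 ± 2.89, adjusted p = 0.0174), SFTPC, a surfactant protein gene (9.85 ± 3.29, adjusted p = 0.0456), and IHH, a hedgehog ligand (9.37 ± 2.22, adjusted p = 0.0109), which rose from 0.163 ± 0.196 to 91.8 ± 20.6 TPM. The call of CYP19A3 was lost without any 1 of 4 libraries (highest adjusted p = 0.0666, without Day 3 replicate 3), that of SFTPC without any 1 of 7 (0.138, without Day 3 replicate 2) and that of IHH without Day 3 replicate 2 (0.0517). AMH (0.87 ± 1.03, adjusted p = 0.558) and FSHR (3.48 ± 1.24, adjusted p = 0.0581) did not pass, though FSHR passed in 4 fits leaving out 1 library (lowest adjusted p = 0.00139, without Year 1 replicate 1).

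Stromal and vascular lists were also placed higher at Puberty. Smooth muscle genes rose in 11 of 20 cases and none fell (camera adjusted p = 6.15e-06, and adjusted p = 0.277 with an estimated correlation), with ACTA2, a contractile actin, at 3.09 ± 0.51 (adjusted p = 0.0022). In the extracellular matrix list 9 of 41 rose and 1 fell (camera adjusted p = 0.00363, and adjusted p = 0.343 with an estimated correlation); the proteoglycan gene VCAN rose by 4.16 ± 0.44 (adjusted p = 0.000294) and the basement membrane collagen COL4A1 by 2.44 ± 0.29 (adjusted p = 0.000522). The endothelium list had 6 of 24 members that rose and 2 that fell, and the macrophage list 5 of 19 and 1; both were placed higher (adjusted p = 0.00363 and 0.00204), with adjusted p = 0.595 for each under an estimated correlation. Cytosolic ribosome genes rose in 3 of 46 cases (camera adjusted p = 0.000575, and adjusted p = 0.721 with an estimated correlation). Immediate early and heat shock genes, which respond to stress and handling, rose in 7 of 25 cases (adjusted p = 0.00363, and adjusted p = 0.596 with an estimated correlation), a call lost without Puberty replicate 3 (adjusted p = 0.192).

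In the surface epithelium list 13 of 18 fell and none rose, and in the oviduct cilia list 11 of 17 fell and none rose (camera adjusted p = 6.15e-06 for both; adjusted p = 0.277 and 0.343 with an estimated correlation). The stem-cell receptor gene LGR5 fell by 5.56 ± 0.78 (adjusted p = 0.00104) and the ciliary dynein gene DNAH11 from 12 ± 2.47 to 0.503 ± 0.114 TPM (adjusted p = 0.00027). The largest falls outside the lists included TKTL1, a transketolase-like gene, from 396 ± 183 to 7.18 ± 0.326 TPM (log2 change -5.45 ± 0.91, adjusted p = 0.00227), and ST6GAL2, a sialyltransferase gene, at -5.21 ± 0.89 (adjusted p = 0.00246). No call was made for the cholesterol synthesis, prostaglandin, cell cycle, lymphocyte, erythrocyte, adipocyte, skeletal muscle, nerve and glia, glycolysis and hypoxia, oxidative phosphorylation, interferon response, imprinted and fetal growth, or hormone receptor lists, whose lowest adjusted p was 0.0658. The glycolysis and hypoxia list gained a call in 6 fits leaving out 1 library (lowest adjusted p = 0.0176, without Pregnancy replicate 3) and the cell cycle list in 1 (9.44e-05, without Puberty replicate 3). Of these, the erythrocyte, adipocyte and hormone receptor lists had a median and a mean of opposite sign. Among KEGG terms, 33 of 335 were enriched among genes that rose (Fisher's exact test), led by transcriptional misregulation in cancer (43 of 160 genes, adjusted p = 0.00065). They included focal adhesion (45 of 191 genes, adjusted p = 0.003) and ovarian steroidogenesis (15 of 48, adjusted p = 0.0168). In a trial with calls enriched by design in focal adhesion alone, 28 other terms also passed. The number of terms is therefore not a number of separate processes. Among genes that fell 3 terms were enriched, led by olfactory transduction (26 of 63, adjusted p = 8e-05).

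In all, 4509 genes changed between Day 3 and Puberty, 1807 higher and 2702 lower, against 1390 and 2881 with upper-quartile scaling. The count was 2644 without Day 3 replicate 2, 2964 without Day 3 replicate 3, 2918 without Puberty replicate 1 and 2933 without Puberty replicate 2. It was higher, at 7872, with only the 2 stages fitted, 9222 with limma voom, and 8378 without both Year 1 replicate 1 and Pregnancy replicate 3. The authors' deposited table has 8532 genes at q under 0.05 for this pair.

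**Figure D4:**
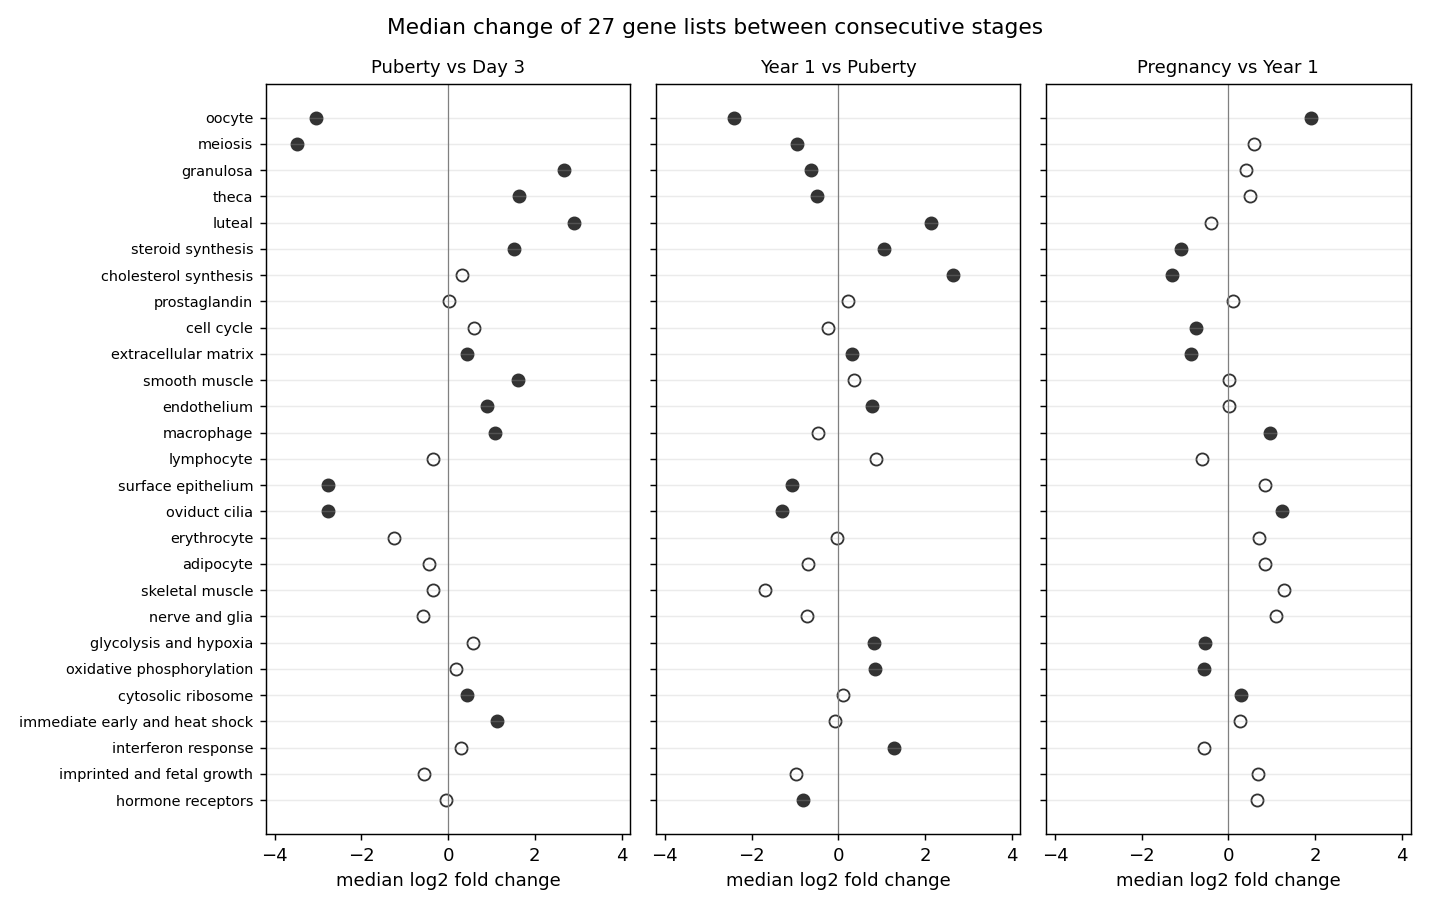
Median log2 fold change of the tested members of 27 gene lists (horizontal axis) in 3 comparisons of consecutive stages; filled points were called by camera at the preset correlation and open points were not. The oocyte list lies at -3.05, -2.40 and 1.91 in the 3 comparisons, and none of the calls holds with an estimated correlation.

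From Puberty to Year 1, 3 germ-cell genes fell. DDX4 fell from 5.86 ± 0.869 to 1.10 ± 0.123 TPM (log2 change -1.94 ± 0.22), and MAEL fell by 2.75 ± 0.33 and GTSF1, another piRNA pathway gene, by 3.20 ± 0.38. PLPP3, a lipid phosphatase gene, rose from 74 ± 4.29 to 138 ± 3.35 TPM (log2 change 1.35 ± 0.16). The adjusted p was 0.0226 for each of these 4 genes (edgeR), no others passed, and none of the 4 kept its call without each library. STAR (5.35 ± 2.28, adjusted p = 0.141), HSD3B1 (4.68 ± 1.66, adjusted p = 0.0983) and CYP11A1 (3.63 ± 1.46, adjusted p = 0.124) had large fold changes that did not pass, with Year 1 replicate 1 near the Puberty level for each. On leaving out 1 library, HSD3B1 passed in 2 fits (lowest adjusted p = 0.0229, without Year 1 replicate 1), CYP11A1 in 2 and STAR in 1 (0.0321 and 0.0332, without Pregnancy replicate 3). In the cholesterol synthesis list 24 of 25 members had positive changes and none passed over all genes, against 21 adjusted over the list alone (camera adjusted p = 4.75e-11, and adjusted p = 0.412 with an estimated correlation). Its library median (log2, centred on all libraries) was 2.84 and 2.44 in Year 1 replicates 2 and 3, the libraries with high STAR, against -0.22 in replicate 1 and -1.02 to -0.58 at Puberty. In the oxidative phosphorylation list all 31 tested members had positive changes, with 18 past the threshold adjusted over the list alone (camera adjusted p = 4.85e-11, and adjusted p = 0.432 with an estimated correlation). In the oocyte list 2 of 27 fell (14 fell and 2 rose adjusted over the list alone; camera adjusted p = 6.03e-10, and adjusted p = 0.412 with an estimated correlation), and in the meiosis list 0 of 21. The oocyte median was -3.76 and -2.33 in Year 1 replicates 2 and 3, against -0.83 in replicate 1 and -0.10 to 0.37 at Puberty.

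Camera also placed the luteal, steroid synthesis, extracellular matrix, endothelium, glycolysis and hypoxia, and interferon response lists higher at Year 1, and the meiosis, granulosa, theca, surface epithelium, oviduct cilia and hormone receptor lists lower (adjusted p from 0.000398 to 0.0432); with an estimated correlation the adjusted p ran from 0.412 to 0.699. Of the 15 lists called, 4 lost the call on leaving out 1 library: luteal in 8 fits (highest adjusted p = 0.0828, without Year 1 replicate 2), theca in 2 (0.133, without Year 1 replicate 2), extracellular matrix in 2 (0.0889, without Year 1 replicate 1) and steroid synthesis in 1 (0.15, without Year 1 replicate 1). Year 1 replicate 1 lay within the Puberty range of library medians for the granulosa (1.15), theca (1.21) and luteal (-0.13) lists, against -1.46 and -1.14, -1.71 and -0.70, and 2.22 and 2.33 in replicates 2 and 3. In the luteal list 7 of 19 members rose and 1 fell adjusted over the list alone. In the glycolysis and hypoxia list these were 11 and 1 of 26. Among the 12 lists not called the lowest adjusted p was 0.0816, and median, mean and test differed in sign for the erythrocyte, adipocyte, nerve and glia, and immediate early and heat shock lists. On leaving out 1 library 7 of the 12 gained a call: cell cycle in 2 fits (lowest adjusted p = 3.98e-05) and immediate early and heat shock in 1 (0.000931), both without Puberty replicate 3; macrophage in 2 (0.000389), smooth muscle in 1 (0.00763) and cytosolic ribosome in 1 (0.0302), all without Year 1 replicate 2. The others were imprinted and fetal growth in 4 (0.0148, without Puberty replicate 1) and lymphocyte in 1 (0.0457, without Year 1 replicate 3). The interferon response list had a library median of 2.24 (log2, centred on all libraries) in Year 1 replicate 2, against -0.81 and -0.41 in its stage mates, and was placed lower, not higher, without that library (adjusted p = 0.0266). At an unadjusted p under 0.05 the edgeR count was 4903 genes. After adjustment, in place of 4, it was 6159 without Year 1 replicate 1, 2675 without Pregnancy replicate 3, 8262 without both, and 0 without Year 1 replicate 2 or 3, Puberty replicate 1, 2 or 3, Day 3 replicate 1 or 2, or Pregnancy replicate 1. It was 1 without Day 3 replicate 3 and 2 without Pregnancy replicate 2. DESeq2 called 3302 genes, limma voom with quality weights 9352, and the authors' deposited table has 1980 at q under 0.05.

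Between Year 1 and day 105 of pregnancy, 7 of 41 extracellular matrix genes fell and 34 did not pass. Of 27 oocyte genes 2 rose and 2 fell, and 2 of 19 macrophage genes rose. The matrix genes that fell were COL4A1 (-1.46 ± 0.28), COL4A2 (-1.30 ± 0.26), COL3A1 (-1.85 ± 0.37), VCAN (-1.82 ± 0.40), LAMC1 (-0.88 ± 0.16), BGN (-1.22 ± 0.23) and SPARC (-0.96 ± 0.22), which made 7 of the 41 tested in the extracellular matrix list (16 fell and 1 rose adjusted over the list alone; camera adjusted p = 1.42e-05, and adjusted p = 0.44 with an estimated correlation). LDHA, which converts pyruvate to lactate, fell from 202.8 ± 30.4 to 79.1 ± 9.03 TPM (log2 change -1.50 ± 0.18, adjusted p = 0.0269), the lowest adjusted p of the comparison. PGR, the progesterone receptor gene, changed by -2.76 ± 0.51 and KIT, a receptor of oocytes and other cells, by -2.74 ± 0.37 (adjusted p = 0.0401 and 0.0354). INSRR, an insulin receptor relative, fell by 7.20 ± 1.45 (adjusted p = 0.0438), with Year 1 libraries between 0.55 and 31.4 TPM. The glycosyltransferase gene MGAT4C rose by 4.45 ± 0.80 (adjusted p = 0.0401), and CPXM2 and FGL2 rose by 3.70 ± 0.79 and 3.07 ± 0.65 (adjusted p = 0.046 for both). DDX4 rose by 1.19 ± 0.22 (adjusted p = 0.0401), from 1.10 to 2.79 ± 0.535 TPM, and the prostaglandin receptor gene PTGER3 by 3.68 ± 0.69 (adjusted p = 0.0401). MAEL and GTSF1 rose by 1.63 ± 0.33 and 1.93 ± 0.38 (adjusted p = 0.0443 and 0.0431), and S100B, a glial marker, by 1.60 ± 0.29 (adjusted p = 0.0401). In the macrophage list MRC1, the mannose receptor (0.98 ± 0.17), and VSIG4, a complement receptor (1.58 ± 0.36), rose of 19 tested (camera adjusted p = 0.00175, and adjusted p = 0.641 with an estimated correlation), a list call lost without Year 1 replicate 1 (adjusted p = 0.252).

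In the oocyte list 2 members rose and 2 fell of 27 (camera higher, adjusted p = 0.000101, and adjusted p = 0.631 with an estimated correlation). Its library median was -1.42 in Pregnancy replicate 3, below the -0.83 of Year 1 replicate 1, and -3.76 and -2.33 in Year 1 replicates 2 and 3. The cholesterol synthesis and oxidative phosphorylation lists were placed lower (adjusted p = 2.12e-06 for both, and adjusted p = 0.631 for both with an estimated correlation); this comparison shares the Year 1 libraries with the one before it, so opposite directions arise in part from the shared libraries. Pregnancy replicate 3 had medians of 1.35 and 0.62 in these 2 lists, above the -0.22 and 0.31 of Year 1 replicate 1. The steroid synthesis, cell cycle, and glycolysis and hypoxia lists were also placed lower and the oviduct cilia and cytosolic ribosome lists higher (adjusted p from 0.000331 to 0.0241); with an estimated correlation the adjusted p ran from 0.44 to 0.874. Among the 17 lists not called the lowest adjusted p was 0.0715, and median, mean and test differed in sign for the granulosa, endothelium, prostaglandin, and immediate early and heat shock lists. On leaving out 1 library 6 of the 17 gained a call: granulosa (lowest adjusted p = 2.81e-05) and theca (0.000132) without Year 1 replicate 1, luteal (0.000179), meiosis (0.0204) and hormone receptors (0.0424) without Pregnancy replicate 3, and interferon response in 2 fits (4.09e-11, without Year 1 replicate 2). In the cell cycle list 40 of 42 members had negative changes and none passed; without Year 1 replicate 1 its median was 0.11 (adjusted p = 0.781), and the call was lost in 1 other fit. The steroid synthesis call was lost in 3 fits (highest adjusted p = 0.194, without Year 1 replicate 1) and the cytosolic ribosome call in 4 (0.442, without Pregnancy replicate 2). Among KEGG terms 1 of 335 was enriched among genes that fell, N-glycan biosynthesis (7 of 50, adjusted p = 0.0152), and none among genes that rose.

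The comparison of Pregnancy with Year 1 gave 465 changed genes, 210 higher and 255 lower, with adjusted p-values of 0.0269 or more. With upper-quartile scaling the larger part turned, at 172 higher and 154 lower. No gene passed without Day 3 replicate 1, 2 or 3, Puberty replicate 2, Year 1 replicate 2 or 3, or Pregnancy replicate 1; 12 passed without Puberty replicate 1, 18 without Puberty replicate 3, 9 without Pregnancy replicate 2, 4913 without Year 1 replicate 1, 2942 without Pregnancy replicate 3 and 8005 without those last 2 together. None of the 23 genes named by the rule and called here kept its call without each library. DESeq2 called 2907 genes and limma voom with quality weights 8825. EdgeR called 131 without a count filter and 0 when only the 2 stages were fitted. The authors' deposited table has 779 genes at q under 0.05.

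Across longer intervals, 7532 genes differed between Year 1 and Day 3, 3767 higher and 3765 lower at Year 1. With upper-quartile scaling, which shifted all log2 changes by -0.23 here, the split was 2785 higher and 4424 lower. Pregnancy and Day 3 differed in 5335 genes, 2494 higher and 2841 lower, against 1774 and 3104 with upper-quartile scaling, a shift of -0.13. The count for Pregnancy and Day 3 was 3302 without Day 3 replicate 2 and 3522 without Day 3 replicate 3. At Year 1 against Day 3, 21 of 27 oocyte genes fell and 1 rose, and 18 of 25 cholesterol synthesis genes rose. The cholesterol synthesis library median (log2, centred on all libraries) was 2.84 and 2.44 in Year 1 replicates 2 and 3. It was -0.22 in replicate 1 and -0.93 to -0.80 at Day 3. In Pregnancy against Day 3, 37 of 46 cytosolic ribosome genes and 16 of 24 endothelium genes rose, with none falling in either list. The cytosolic ribosome median was 0.69 and 0.68 in Pregnancy replicates 1 and 2 but -0.25 in replicate 3, against -0.49 to -0.42 at Day 3.

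Pregnancy and Puberty did not differ in any gene by edgeR's test (lowest adjusted p = 0.331), with 1156 genes at an unadjusted p under 0.05. DESeq2 called 97 genes, limma voom with quality weights 117 and the authors' deposited table has 82 at q under 0.05.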

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

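Results are counts of changed genes and of called lists, named genes and single lists; a count is said to move when it changes by more than 1.5 times. RLE and upper-quartile scaling and a minimum count of 50 moved no count of genes. Without a count filter Pregnancy vs Year 1 gave 131 genes. DESeq2 gave 3302 genes for Year 1 vs Puberty, 2907 for Pregnancy vs Year 1 and 97 for Pregnancy vs Puberty. On simulated counts for Year 1 vs Puberty DESeq2 called 58 of 15213 unchanged genes and edgeR 6. There DESeq2 also recovered more true changes, 26 of 67 at 2-fold, 56 of 67 at 4-fold and 63 of 66 at 8-fold. EdgeR recovered 9, 43 and 58 in the same order. Limma voom with quality weights gave 9222 for Puberty vs Day 3, 9352 for Year 1 vs Puberty, 8825 for Pregnancy vs Year 1, 11424 for Year 1 vs Day 3, 8703 for Pregnancy vs Day 3, 117 for Pregnancy vs Puberty and 13644 for any stage; its weights were lowest for Year 1 replicate 1 (0.125) and Pregnancy replicate 3 (0.158). A fold threshold of 2, a stricter hypothesis, gave 1293, 0, 0, 2875 and 1639 for the first 5 of these pairs. Fitting only the 2 stages compared gave 7872 for Puberty vs Day 3, 0 for Year 1 vs Puberty and 0 for Pregnancy vs Year 1. Beyond the construction of the fold threshold, the cause was not tested.

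Leaving out 1 library gave 2644 to 6128 genes for Puberty vs Day 3, 0 to 6159 for Year 1 vs Puberty, 0 to 4913 for Pregnancy vs Year 1, 5583 to 9461 for Year 1 vs Day 3, 3302 to 7062 for Pregnancy vs Day 3 and 4544 to 10583 for any stage. Leaving out Year 1 replicate 1 and Pregnancy replicate 3, chosen after seeing the data, gave 8378 for Puberty vs Day 3, 8262 for Year 1 vs Puberty, 8005 for Pregnancy vs Year 1, 3 for Pregnancy vs Puberty and 12249 for any stage. Of the genes named by the rule and called, 33 of 45 for Puberty vs Day 3 kept their call without each library, and none of 4 for Year 1 vs Puberty.

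The replicate numbers did not pair the sows: deviations of same-numbered libraries correlated between -0.393 and 0.402, 5 of 18 pairs were over 0.1, and 4 of 12 libraries correlated best with their own number. With a replicate block, Year 1 vs Puberty and Pregnancy vs Year 1 gave 0 genes each and no other count moved.

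Camera at the preset correlation called 14, 15 and 10 lists in the 3 consecutive comparisons; with an estimated correlation it called 0, 0 and 0. Directions turned in a few cases. Each turned when Year 1 replicate 1, Pregnancy replicate 3, both, or Year 1 replicate 2 was left out, or with limma voom, which gave the first 2 low weights. Why those libraries differed from their stage mates was not settled. CYP17A1 for Year 1 vs Puberty was -3.33 with limma voom, -3.05 without Year 1 replicate 1 and -3.06 without that library and Pregnancy replicate 3, against 0.53; leaving out 1 library gave -3.05 to 1.43. PTGFR for Pregnancy vs Year 1 was -3.13 with limma voom and -3.67 without both libraries, against 1.05; leaving out 1 library gave -3.10, without Pregnancy replicate 3, to 1.67. The cell cycle list for Pregnancy vs Year 1 had a median of 0.11 without Year 1 replicate 1 and 0.32 without both libraries, and -1.16 to 0.11 over all libraries left out. Without Year 1 replicate 2 the interferon response list was at -0.27 for Year 1 vs Puberty and 0.97 for Pregnancy vs Year 1, within ranges of -0.27 to 1.80 and -0.97 to 0.97. At 3 sows per stage, simulated 2-fold changes were mostly missed, so small changes may go uncalled: 5 of 67 were recovered for Pregnancy vs Year 1, where the settings gave 0 to 8825 genes.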

Other observations

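The tests of library depth, exchanged libraries, luteal share, germ-cell composition and oviduct markers were chosen after the results were seen, and the germ-cell genes and oviduct markers were drawn up after values of members had been seen; only the counts of other splits were chosen before.

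Puberty replicate 3 had TIMP1 at 2933.2 TPM, against 373 and 336.4 TPM in its stage mates. The nearest library to it was Pregnancy replicate 2 (0.737), with its stage mate Puberty replicate 2 almost as near (0.746). TIMP1, an inhibitor of matrix proteases, was at 27278.1 and 17951.5 TPM in Year 1 replicates 2 and 3 and at 493.2 TPM in Pregnancy replicate 3, so that it did not follow STAR between those 3 libraries. SFTPC, the surfactant protein C gene of lung, rose from 0.24 ± 0.0954 TPM at Day 3 to 186 ± 274 TPM at Puberty (SD, n = 3), with libraries between 2.26 and 501 TPM; its edgeR adjusted p was 0.0456, and 0.138 without Day 3 replicate 2.

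Other splits of the libraries bear on the counts of changed genes. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. For Puberty vs Day 3 the real split gave 4509 genes and the highest other 1, so 1 of 10 was as large. The same number, 1 of 10, held for Year 1 vs Day 3 (7532 against 0) and Pregnancy vs Day 3 (5335 against 1). For Year 1 vs Puberty 2 of 10 splits gave as many as the real 4, and the highest gave 1433; it put Year 1 replicate 1 with Puberty replicates 1 and 2. For Pregnancy vs Year 1 2 of 10 gave as many as the real 465, and the highest gave 6166; it exchanged Year 1 replicate 1 with Pregnancy replicate 3, which points to a structure of the samples other than the stages. For Pregnancy vs Puberty all 10 gave 0. For any stage, 1 of 100 drawn splits, the real one, reached 7220. Most such splits mix the Day 3 libraries, which lay far from all others, into other groups, which would lower their counts. The result therefore does not show that differences among Puberty, Year 1 and Pregnancy exceed those of other splits. The highest of the other drawn splits gave 4509 and put Year 1 replicates 2 and 3 with Pregnancy replicate 3.

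Luteal and steroid synthesis genes differed between libraries of the same stage. Library depth is argued against as the cause, since the totals of these 6 libraries differed by at most 1.08-fold. The rule for an exchange of Year 1 replicate 1 with Pregnancy replicate 3 was widened to count the exchanged split after its first form had argued against an exchange. By the widened rule an exchange cannot be told apart from a difference between the sows or the fragments sampled. Exchanging them gave the 6166 genes, but that split also sets the libraries rich in luteal transcripts against those poor in them. It could give more changed genes whatever set these libraries apart, so the count cannot decide for an exchange. Year 1 replicate 1 differed over 8-fold from Pregnancy replicates 1 and 2 in 121 and 108 genes. From its own stage mates it differed in more, 1134 and 641. Pregnancy replicate 3 still differed over 8-fold from Year 1 replicates 2 and 3 in 702 and 474 genes. From its own stage mates that library differed in fewer, 421 and 417. The 8 same-stage pairs outside the exchange differed in 12 to 163, and only 1 of those pairs held 2 libraries rich in luteal transcripts. RLN2 (49365.1 TPM against 292.8 and 265.4) and MSMB (549.1 TPM against 36138.7 and 30835.2) ran against an exchange. A larger share of luteal tissue in the fragment sampled may also account for the difference. The oocyte, granulosa, theca and surface epithelium lists, 4 of 4, had lower medians in Year 1 replicates 2 and 3 and Pregnancy replicate 3 than in each stage mate. For the Year 1 libraries a sow's cycle state, not given in the labels and not tested, would give this too. It does not apply to the Pregnancy libraries, which were all labelled day 105 of pregnancy.

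Early germ-cell and meiosis genes may have fallen more than genes of the growing oocyte between Day 3 and Puberty, which dilution of a germ-cell pool of fixed composition would not give. The means of 19 and 15 genes changed by -3.61 and -1.58 (log2 CPM), a difference of -2.03. The libraries of the 2 stages did not overlap. The combined SD was 1.17, which is the spread of a difference between single libraries and not between stage means. The rule asked for a difference beyond 2 such SDs, so by it dilution cannot be told apart from a change in composition.

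In the surface epithelium list 13 of 18 tested genes, and in the oviduct cilia list 11 of 17, were higher at Day 3 than at Puberty, and none was lower. Camera did not call either list with an estimated correlation (adjusted p = 0.277 and 0.343). Oviduct or rete tubules sampled with the small ovary are a candidate source. Of 8 markers 6 had values, and 3 of these were higher at Day 3 (PAX2, WNT7A and MSX2). WNT7A was the most abundant of these 3 at 22.9 ± 7.74 TPM (SD, n = 3), against 1.42 ± 0.252 TPM at Puberty. PAX2 was near the floor, at 0.66 ± 0.262 TPM at Day 3 and 0.00667 ± 0.0115 TPM at Puberty. OVGP1, an oviduct secretory gene, was at 5.40 ± 1.32 TPM and 5.42 ± 1.87 TPM, and EMX2 (log2 change -0.08, edgeR adjusted p = 0.91) and CDH16 (-1.34, adjusted p = 0.258) did not pass. PAX8 and MUC16 were not among the gene symbols of the deposited table. The ovary's own epithelium and rete can express some of these genes, so the source cannot be told apart.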
